A study of Gallus gallus with 12 samples.

How the data were processed

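RNA from crude tibial bone marrow of female chickens of 2 lines was hybridised in 2 colours on 6 slides, each with 1 sample of a White Leghorn layer line and 1 of a Cobb broiler line. The 12 samples form 2 groups of 6. The slide and dye of every sample are given in its title, and slides are numbered here 1 to 6 by the replicate number of their samples. On slides 1, 5 and 6 the broiler sample carried Alexa Fluor 647 and the layer sample Alexa Fluor 555, and on slides 2, 3 and 4 the dyes were exchanged, per the labels. Titles and sample characteristics give an age of 60 weeks, while the collection note of every sample gives euthanasia at 15 weeks, and the labels do not settle the difference. Per the labels' protocols, total RNA was extracted with Trizol, reverse transcribed with oligo(dT) and random hexamers and labelled indirectly. Broilers were feed-restricted from 6 weeks and layers fed freely, so line and feeding cannot be told apart. The labels do not say whether each sample came from its own hen, so the p-values measure only the spread between these samples, which may be technical.

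The deposited table has 1 column per sample and 15769 rows, of which 2143 hold a value in all 12 columns and 13626 are blank in all 12. The deposited values are natural log intensities of 1 channel each. The log base is not given in the sources used here and was found from the values. On each slide, the 60 lowest distinct sums of both channels were taken as logs of products of 2 whole-number intensities. With base e, 100% of these products were whole within 0.02 on all 6 slides, while bases 2 and 10 reached at most 23.3%. The same step gave each spot's mean intensity in scanner units, as the geometric mean of both channels. The scanner, the treatment of background, the normalization and the filter behind the blank rows are not given in the sources used here. Column medians lay between 2.91e-05 and 0.00394 on the natural log scale. Values were divided by the natural log of 2, and all differences are on the log2 scale.

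Before the data were examined, a rule was set by which the table counted as normalized if the median ratio of every slide lay within 0.1 of 0 and a loess of the ratio on brightness spanned under 0.5. The medians of Alexa Fluor 647 over 555 lay between -0.033 and 0.016 and the largest span was 0.12, so the deposited values were used as they were. The log2 ratio of broiler over layer was taken within each slide, which makes the slide a block that pairs its 2 samples. Columns of the same slide correlated across clones at 0.979 to 0.990 and columns of different slides at 0.907 to 0.982. The ratio was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the line as the mean and the dye orientation as a term, which left 4 residual and 2.11 prior degrees of freedom. Benjamini-Hochberg adjustment ran over all clones tested, with a threshold of 0.05. Of 163 rows with control names (plant proteins, chicken genomic DNA and the label PEN), 2 held values and were left out of the tests, which ran on 2141 clones. Rows are called clones after the form of their identifiers. For some comparisons the clones were divided into 4 brightness classes of 535 or 536 clones by their mean level.

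The table does not pair its identifiers with genes, and 0 of them matched the reference gene table of the chicken assembly GRCg7b. The 21 gene lists fixed before the data were examined, among them markers of red cells, heterophils, osteoclasts, bone matrix, lymphocytes, fat and muscle, were therefore not testable (0 of 21). The rule for named genes asked for the 12 largest changes on each side among those past the threshold, for the 5 of smallest p where fewer than 3 passed on a side, and for up to 4 members of each list. Without gene names, only the 2 clones of smallest p on each side are named. In place of the lists, a choice made after the data had been seen, clones were grouped by the start of their identifiers into 4 groups. These were tested with camera at a preset correlation of 0.01 and with an estimated one. What the prefixes stand for is not given in the sources used here.

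The fit was tested on simulated data, in 20 draws with the errors of the 2141 clones and 200 clones changed by known amounts. It recovered 74.2% of clones changed by 0.25, 94.3% of those changed by 0.5 and 98.8% of those changed by 1 on the log2 scale, and 4.22% of its calls were false. With 20 clones changed by 0.5, it recovered 83%. The draws treat clones and slides as independent, while the real ratios of slides 2 and 3 correlated at 0.692. These shares therefore hold only for independent slides. Alternatives set before the data were examined were loess (span 0.3), quantile and median normalization, a filter on dim clones, other block and dye terms, other variance moderation, stricter thresholds and each slide left out. Those added afterwards were slides 2 and 3 averaged or left out, the control spots tested, the random block with each slide left out, and whole-number intensities less the dimmest spot of the slide plus 50. The number of arrays limits the precision of every value.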

Results

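Gene expression in the bone marrow of hens was compared between a White Leghorn line bred for egg laying and a Cobb line bred for meat. The marrow was crude, taken from the whole tibia, and can hold blood-forming, bone and fat cells. The 6 samples of each line were measured on 6 slides that each carried 1 sample of both lines, with the dyes exchanged between 3 slides and the other 3. Values were given for 2143 of 15769 spots. The dimmest spot of a slide had a mean intensity of 150.0 to 259 scanner units and the brightest 15557 to 31474. Between 44.9% and 71.3% of the spots of a slide lay within 2-fold of its dimmest spot.

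The clones came from 4 groups of identifiers, with 733 clones named DT40subNB, 679 named C0004, 659 named Pat and 70 named DKFZ426. DT40 is also the name of a chicken B-cell line. DT40subNB clones were the brightest group, with a median intensity of 574 units, against 390 for Pat, 352 for DKFZ426 and 335 for C0004 clones. Of the DT40subNB clones, 46.8% fell in the brightest of the 4 brightness classes, against 19.0% of the Pat, 9.13% of the C0004 and 7.14% of the DKFZ426 clones.

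The question of the study was which transcripts differ between the marrow of the 2 lines. With limma, 0 of 2141 clones passed an adjusted p of 0.05, and the smallest adjusted p was 0.168. At an unadjusted p under 0.05 there were 243 clones, 88 higher and 155 lower in broiler, where 107 would be expected with no difference. This split depended on centring, with 109 of 213 clones higher after loess and 108 of 223 after median centring. The median size of the difference was 0.044 on the log2 scale, and the estimates ran from -1.18 to 0.65. On the deposited values, the 95% interval lay within 2-fold either way for 2128 clones (99.4%) and within 1.5-fold for 2045 clones (95.5%). These intervals bound the ratios as deposited, in which background may remain. They also take the 6 slides as independent, while the ratios of slides 2 and 3 correlated at 0.692. Subtracting the level of a slide's dimmest spot widens dim ratios by construction, and no such counts are given for it. With the slide as a random block, 40 clones passed, 19 higher and 21 lower in broiler, and that count was 0 without slide 1, 11 without slide 2, 16 without slide 3, 97 without slide 4, 14 without slide 5 and 2 without slide 6.

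The clones of smallest p on each side did not pass the adjustment and are given as values. C0004102_E4 stood at 0.30 ± 0.15 log2 (SD, n = 6 slides) in broiler relative to layer, a ratio of 1.23, and lay between 0.13 and 0.48 on all 6 slides. Pat-15_f5 stood at 0.28 ± 0.21, a ratio of 1.21, with 5 of 6 slides above 0 and slide 4 at -0.060. Pat_10B6 stood at -0.44 ± 0.16, a ratio of layer over broiler of 1.35, and lay between -0.71 and -0.23. Pat-20_b7, the brightest of the 4 at a median of 1685 units, stood at -0.18 ± 0.10 and was below 0 on all 6 slides. The adjusted p of all 4 clones was 0.168 with limma. With the slide as a random block, C0004102_E4 (adjusted p = 0.0142), Pat-15_f5 (0.0208) and Pat_10B6 (0.0141) passed.

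**Figure D1:**
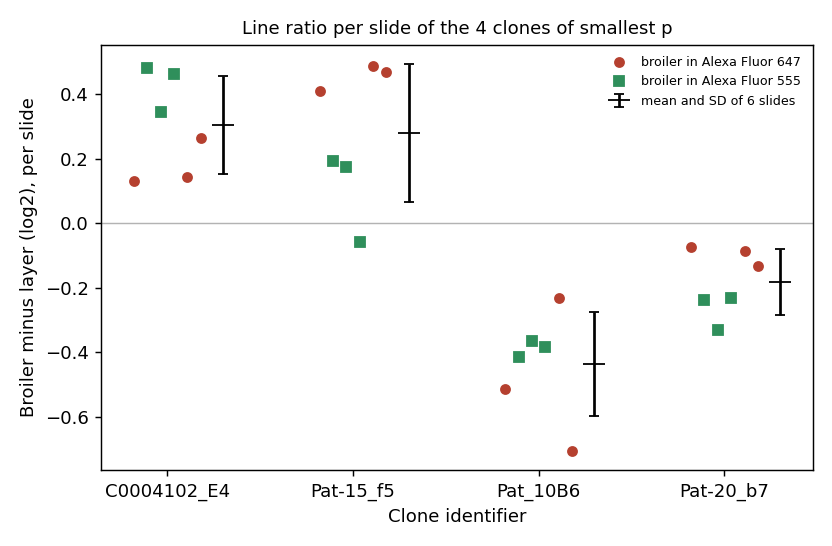
Log2 ratio of broiler over layer on each of the 6 slides (vertical axis) for the 4 clones of smallest p (horizontal axis). Circles are slides with the broiler in Alexa Fluor 647, squares those with it in Alexa Fluor 555, and the bars give mean and SD; slide 4 of Pat-15_f5, at -0.060, is the lone point on the other side of 0 from its mean.

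As groups, the clones did not pass a test for a shift between the lines. The mean of the group's 6 slide medians was -0.016 ± 0.017 log2 (SD) for Pat, -0.011 ± 0.020 for DKFZ426, -0.0085 ± 0.042 for DT40subNB and -0.0082 ± 0.016 for C0004 clones. Camera gave adjusted p-values of 0.551 for Pat and C0004 and 0.637 for DKFZ426 and DT40subNB, and 0.759 for all 4 with an estimated correlation. Without slides 2 and 3, a setting chosen after the data had been seen, C0004 clones passed at 0.0079 (adjusted p = 0.0483). Camera, which sets a group against the other clones, ranked C0004 and DT40subNB upwards although their medians lay below 0. The median difference over clones changed sign with centring for C0004 (-0.0031 as deposited and 0.0084 after loess), DT40subNB (-0.0060 and 0.0050) and DKFZ426 (-0.0094 and 0.0035), and stayed below 0 for Pat (-0.016 and -0.0036). An exact two-sided sign permutation over the 6 slides, which can go no lower than 0.0312, gave p = 0.125 for Pat, 0.25 for DKFZ426, 0.281 for C0004 and 0.656 for DT40subNB, or 0.375 for the first 3 and 0.656 for the last after adjustment. On the 3 slides with the broiler in Alexa Fluor 647 the DT40subNB median was -0.025, -0.034 and -0.073, and on the other 3 it was 0.033, 0.029 and 0.019.

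The dye exchange gave the line ratio in each orientation separately. Across clones, which are not independent replicates, the mean ratios of the 2 orientations correlated at r = -0.193 (rho = -0.260). The correlation was -0.363 among DT40subNB, -0.109 among C0004, 0.057 among DKFZ426 and 0.10 among Pat clones. From the dimmest to the brightest class of clones it was -0.028, 0.120, 0.0054 and -0.380. Over all clones it was -0.0709 without slide 5 and -0.0878 with the floor of each slide subtracted. The dye orientation term enters the 2 orientations with opposite sign. The correlation is therefore below 0 where that term varies more over clones than the line term. Net of error variance, with slides taken as independent, the variance over clones was 0.0117 for the dye orientation term and 0.00638 for the line term. A correlation below 0 thus does not by itself show that line differences are absent.

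**Figure D2:**
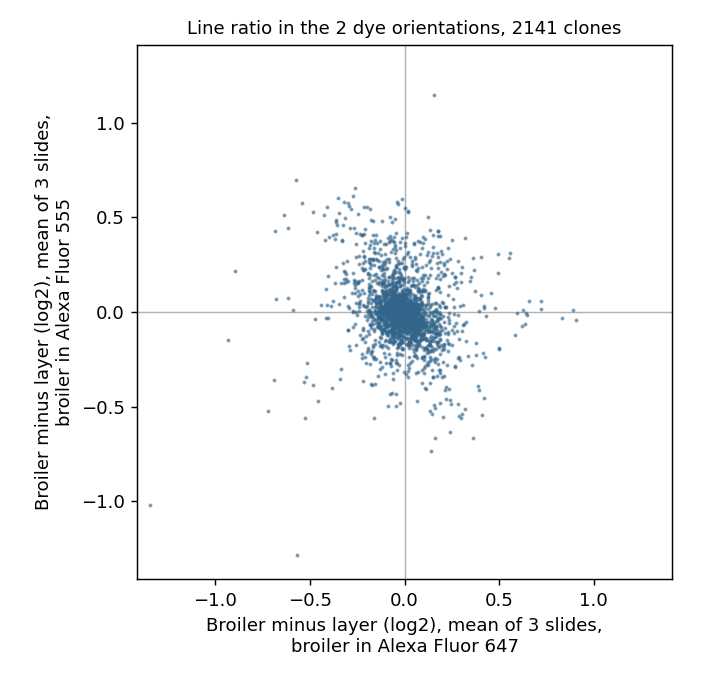
Mean log2 ratio of broiler over layer over the 3 slides with the broiler in Alexa Fluor 647 (horizontal axis) and over the 3 slides with it in Alexa Fluor 555 (vertical axis), with 1 point for each of 2141 clones. The points do not rise from left to right, with r = -0.193.

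The technical comparison, between the dyes, passed on 160 clones, 66 brighter in Alexa Fluor 647 and 94 brighter in Alexa Fluor 555 (limma, smallest adjusted p = 0.00423). DT40subNB clones made up 105 of them, of which 26 were brighter in Alexa Fluor 647. The share of clones with a dye difference was 14.3% among DT40subNB, 4.12% among C0004, 3.79% among Pat and 2.86% among DKFZ426 clones. DT40subNB clones as a group were shifted towards Alexa Fluor 555, with a median of -0.033 (camera adjusted p = 0.000154, or 0.0907 with an estimated correlation). Without slides 2 and 3 this shift was -0.029 (camera adjusted p = 0.117). Pat clones were shifted the other way, at 0.010 (camera adjusted p = 0.0228, or 0.249 with an estimated correlation and 0.106 without slides 2 and 3). Camera sets a group against the other clones, so results of the other groups are not separate from the DT40subNB shift. The Pat shift was 0.0066 without slide 1 and 0.0062 without slide 5, and with the floor of each slide subtracted the shifts were 0.019 for Pat and -0.054 for DT40subNB. C0004 clones, at 0.0085, did not pass (camera adjusted p = 0.115). They passed without the dimmest class (0.022, camera adjusted p = 0.0162), without slide 4 (0.014, 0.0382) and without slide 5 (0.012, 0.0485), and in no other setting. The count of 160 was 1 without slide 1, 0 without slide 2, 2 without slide 3, 167 without slide 4, 4 without slide 5 and 128 without slide 6, and 0 where the slide was not a block.

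The slides differed in how alike their line ratios were across clones. Slides 2 and 3 correlated at r = 0.692 and slides 1 and 5 at 0.457, and the other pairs of like orientation lay between -0.049 and 0.225. The 9 pairs of opposite orientation lay between -0.320 and 0.115. By rank, the pairs separated by dye orientation: rho lay between 0.282 and 0.693 in all 6 pairs of like orientation and between -0.355 and -0.0322 in all 9 of opposite orientation. The SD of the ratio over clones ran from 0.19 on slide 1 to 0.27 on slide 3.

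**Figure D3:**
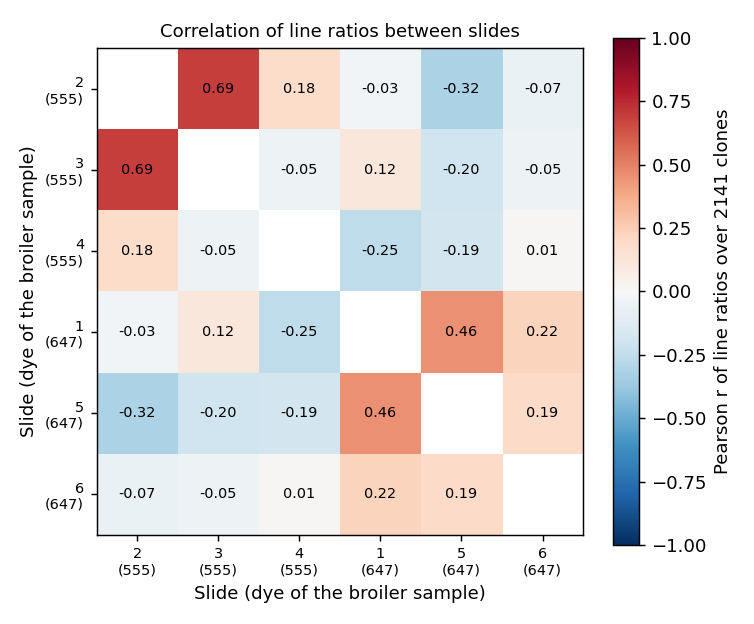
Pearson correlation across 2141 clones of the log2 ratio of broiler over layer between each pair of the 6 slides, as a colour from -1 to 1, with the dye of the broiler sample in brackets on both axes. Slides 2 and 3 have the highest value, 0.692, and pairs of opposite orientation lie between -0.320 and 0.115.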

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

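The control spots and the counts of clones over 1 log2 were examined only after the data had been seen. In 2 of 14 sets of 6 slide values, 1 slide lay further from the rest than Dixon's 95% critical value allows, and chance alone gives this in about 1 in 20 such sets. Both sets belong to spots with plant protein names that were left out of the tests. The spot NAC1.2 had a log2 ratio of broiler over layer of -1.46 on slide 1 and between -0.065 and 0.15 on the other 5 slides. The spot PRKase.28 had a ratio of 1.74 on slide 6 and between -0.065 and 0.045 on the other 5. Among the 2141 clones, 87 lay over 1 log2 from 0 on exactly 1 slide and 6 on more than 1 slide. Slide 3 held 49 such clones and the other slides 3 to 16 each, and without slide 3 the counts were 44 and 3.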

How the results depend on the processing

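The settings with slides 2 and 3 averaged or left out, with the control spots, with the floor subtracted, with the random block less 1 slide and with the identifier groups were chosen after the data had been seen. The line difference gave 0 clones after loess, quantile and median normalization, without the dimmest class, without the dye term, with trended and robust moderation, without moderation and with any 1 slide left out, with smallest adjusted p-values from 0.0622 to 0.342. It also gave 0 with slides 2 and 3 averaged, with the control spots and with the floor subtracted. The 0 at both stricter thresholds followed from the 0 at 0.05 and adds nothing. With no replicate block the unpaired fit gave 0 clones (smallest adjusted p 0.970), and 33 in place of 243 at an unadjusted p under 0.05. The random block gave 40 clones. Without slides 2 and 3 the line gave 2 clones, both higher in broiler, and the C0004 group passed (0.0079, adjusted p = 0.0483, against 0.330 to 0.904 in the other settings); that fit has slide 4 as its only slide with the broiler in Alexa Fluor 555. The dye count of 160 was 95 after loess, 84 after quantile normalization, 282 with the random block, 7 without moderation, 2 with slides 2 and 3 averaged or left out, 0 with no replicate block and 0 to 167 with 1 slide left out. The correlation between orientations was -0.0878 with the floor subtracted and -0.236 to -0.0709 with 1 slide left out. Fits on fewer slides have fewer residual degrees of freedom; otherwise the cause was not tested. All tested clones had all 12 values, so the filter on missing values removed none. The offset for linear values did not apply, and the gene lists were not run. Of the spots of a slide, 44.9% to 71.3% lay within 2-fold of the dimmest. Subtracting the floor, which widens dim ratios by construction, gave 0.39 for C0004102_E4, 0.40 for Pat-15_f5, -0.58 for Pat_10B6 and -0.20 for Pat-20_b7, in place of 0.30, 0.28, -0.44 and -0.18. The background level is not given in the sources used here, so which is closer stays open.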

Other observations

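The share of spots with values differed between the clone groups. It was 40.8% of 1798 DT40subNB spots (95% exact binomial interval 38.5 to 43.1), 33.2% of 1983 Pat spots (31.2 to 35.4), 18.5% of 378 DKFZ426 spots (14.7 to 22.8) and 5.93% of 11447 C0004 spots (5.51 to 6.38). Over the 30 plates of C0004 clones the share ran from 2.34% to 11.7%. The binomial intervals take spots as independent draws and leave out such spread between plates, so they are too narrow where plates differ. The filter behind the blank spots is not given in the sources used here, so these are not shares of expressed genes.

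The tests below were chosen after the result was seen, except 3: the splits and the simulation for the random block, and the brightness of clones with a dye difference. Exchanging samples within slides gives 31 splits. The 0 clones of the line difference are reached by any split (31 of 31), so the splits decide nothing there; 5 of the 30 others gave 3 to 18 clones, for reasons not tested. At an unadjusted p under 0.05, 3 of 31 splits gave at least the 243 clones of the line difference (highest other 308), so chance cannot be excluded for the excess over 107.

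With the slide as a random block, 40 clones passed, of which 27 had the same sign on all 6 slides, against 129 of all 2141 clones (6.03%). The 40 were picked by p on the same slides, so their like signs are no separate support. Of 31 splits, 2 gave as many clones (highest other 72), so chance cannot be excluded. Leaving out slide 1 took the random-block count to 0. Simulated slides with no line difference, drawn as independent, gave at most 9. That does not exclude unequal correlation within slides or likeness between slides. The split with 72 clones exchanges the samples of slide 4 alone, and that slide's dye-adjusted ratio correlated at -0.254 with the line difference of the other 5 slides, the lowest of the 6 slides (the others 0.0537 to 0.408). This correlation, -0.0745 by rank and -0.552 in the brightest class (the other slides 0.163 to 0.419), restates the counts that raised the question and is no separate evidence. Its dye adjustment was estimated on the same 5 slides as the line difference, so part of the correlation is built in. It therefore gives no ground for samples exchanged on slide 4 or for hens that differ from their line. These 2 cannot be told apart, and an exchange would break the stated balance of 3 samples of each line per dye.

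For the dye difference, 1 of 31 splits, the real one, gave 160 clones (highest other 16). A share of 1 in 31 is the lowest these splits can give, and it assumes that the 6 slides are independent. The count was 2 with slides 2 and 3 averaged and 0 without slide 2, so chance cannot be excluded. A brightness trend does not account for all of it, since 95 clones passed after loess. The share of clones with a dye difference was 17.9% in the brightest and 0.746% in the dimmest class (Fisher's exact p = 4.06e-26). A dye bias that grows with labelled cDNA predicts such a rise, but the line term rose too. Its share of clones at an unadjusted p under 0.05 was 4.10% in the dimmest and 16.4% in the brightest class. A rise with brightness is thus not particular to the dye. The dye share is at an adjusted p under 0.05, so the sizes of the 2 rises cannot be compared. Within the brightest class the dye share was 22.2% of 343 DT40subNB and 10.4% of 192 other clones (Fisher's exact p = 0.000617). Both Fisher tests count clones measured on the same 6 slides as independent. Their p-values therefore do not measure support for a dye bias or for a DT40subNB effect. No biological explanation was tested.

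The line ratios of slides 2 and 3 correlated at 0.692. Taking out the median of each plate, as read from the identifiers, left 0.671. Here all 70 DKFZ426 clones counted as 1 plate, and DT40subNB identifiers without a well letter were taken as plate names. For the other clones the value argues against a shift of whole plates. It cannot address position within a plate or on the slide. Dye bias stays open: the other 2 pairs of that orientation reached at most 0.183, but both hold slide 4, and by rank all 6 pairs of like orientation lay above 0. The same hens or the same RNA on both slides may be a source, with a correlation of 0.330 in the dimmest and 0.789 in the brightest class. A shared labelling or hybridisation batch could give the same values, and the labels name neither, so these and dye bias cannot be told apart.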
